A study of Mus musculus with 2 samples.

How the data were processed

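Messenger RNA was measured by sequencing in 2 libraries of 3T3-L1 cells, a mouse fibroblast-like preadipocyte line that turns into lipid-filled adipocytes under a hormonal cocktail. Per the labels' protocols, cells at passages 10 to 13 were grown in medium with 10% calf serum and kept for 2 days after confluence. For 2 days they then received insulin (1 µg/mL), 0.5 mM of the phosphodiesterase inhibitor IBMX and 0.25 µM of the glucocorticoid dexamethasone, with 10% fetal bovine serum, and insulin alone afterwards. The treated culture received DF, a mixture of several herbs (the sample title calls the preparation DF-GA70), which stayed in the medium up to harvest. The dose of DF and the day of harvest are not given in the sources used here. Libraries were made from 500 ng of total RNA with a Lexogen kit that reads the 3' ends of messenger RNAs (the labels name it both as a SENSE 3' and as a Quant-Seq kit) and sequenced as single 75 nt reads.

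The deposited values are on a log2 scale, and the file headers give a gene symbol and the sample name only. The submitters' processing notes name Bowtie2, edgeR and the mm10 genome build. Their versions, the read counter, the annotation and whether counting used the strand are not given in the sources used here. No label records how the values were normalized. From the values themselves, both libraries appear to have been brought to 1 common distribution (quantile normalization). The highest 140 values, sorted, are identical in both files, and 97.9% of the 12337 ranks above 0 in both hold sorted values within 0.1 log2 units of each other. The depth of each library is unknown, and no counting interval or detection limit was computed. Of the linear values under 1000, 100% in each library lie within 0.001 of a multiple of 1/8. Means over 8 libraries at each rank would give such a grid, so the values may draw on libraries that are not analysed here. Such a normalization removes any difference in total output or in the shape of the distribution between the libraries. Among the highest 140 values, a gene's value then gives only its rank, and an equal value in both libraries means an equal rank. Linear values are 2 to the power of the deposited log2 value. A value of 0 is described as listed at 0. Because the protocol reads transcript ends, values are not divided by transcript length.

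Each group holds 1 library (control and DF), so no difference has a replicate check. No test between the conditions was run and no p-value is given. Differences are DF minus control on the deposited log2 scale, with no pseudocount added. Before the data were examined, the rules of size, the gene lists, the naming rule and most of the alternative settings were fixed. The plan had allowed for read counts or normalized values, and the branch for normalized values was used. A gene was examined when it reached the median of all non-zero values, 8.18 (log2), which is 290.75 on the linear scale, in at least 1 library. It was counted when the difference was at least 2-fold. Members of 33 fixed gene lists were counted as higher or lower at 1.5-fold under the same floor. For each list with at least 3 members above 0 in both libraries, the median difference was set against 10000 random lists of the same size drawn from 20 bins of mean level. That percentile describes these 2 libraries and is no test of the treatment. Bootstrap intervals over members (95%, 2000 draws) treat genes as independent and leave out the variation between cultures. Each gene was also placed among the 200 genes nearest to it in mean level. For genes near the top or bottom of the scale, these were the 200 other genes at that end.

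The genes named are the 10 highest and the 10 lowest of those examined, 15 key genes, and in each list the 2 most abundant members and up to 3 with the largest difference among members counted at 1.5-fold. A few genes that this rule names, and 1 gene family, are not reported here. Predicted genes, Rik clones and pseudogenes were passed over among the highest and lowest. Positions are those of GENCODE vM21 on GRCm38, the assembly that mm10 names; 23376 of the 24421 symbols (95.7%) matched it. Transcript length and the GC content of the last 500 nt came from its longest coding transcript per symbol.

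The procedure was tested on simulated data for this comparison with 11744 genes, in which noise was drawn from the observed differences of genes of similar level. The 2-fold rule recovered 49% of 100 genes changed by 1 log2 unit and 95% of 100 genes changed by 2 log2 units. A change of 1 log2 unit equals the limit, so the noise decides whether such a gene is counted. The rule also counted 5.80% of 6574 unchanged genes. This share is close to the observed one by construction, since the noise came from the observed differences. It is therefore no measure of false calls. The list percentile fell outside the central 95% for 93.5% of 200 lists of 25 genes shifted by 0.4 log2 units and for 5.50% of 200 unshifted lists. The share of unshifted lists was also set by construction, since they were drawn at random with independent noise. Lists whose members vary together were not simulated. Alternatives were pseudocounts on the linear value, other level floors and fold limits, the mean in place of the median, other rules for list members, centring, and removal of trends in GC content and length. Alternatives that need read counts (other scalings, count minimums, counting intervals) were not run. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.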

Results

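The transcriptomes of 3T3-L1 adipocytes kept with or without DF, a multi-herbal preparation described as anti-obesity, were compared to ask how DF affects adipocyte gene expression. There was 1 untreated control library and 1 DF library, so every value is a single measurement without a replicate error. Of 24421 genes listed, 13013 were above 0 in the control library and 12337 in the DF library, and 11744 in both. Rn45s, the precursor of ribosomal RNA, had the highest value in both libraries and made up 9.08% of the summed linear values in each. The equal share follows from the identical highest values in the sorted files, so it does not compare ribosomal RNA content between the libraries. The sequencing depth of each library is unknown. Across genes above 0 in both libraries the values correlated with a Pearson r of 0.949; genes are not independent replicates.

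The DF library differed from the control by at least 2-fold in 173 genes that were higher and 217 that were lower, of 6761 genes examined (2.56% and 3.21%). The median difference was 0.01 log2 units, with an SD of 0.54 across genes, and 78.9% of the genes lay within 1.5-fold. The spread depended on level. Its robust SD was 0.66 log2 units for the 1564 genes with a mean level of 7 to 8, 0.45 for those of 9 to 10 and 0.35 for those of 12 to 14. Without replicates, these spreads hold both the variation between cultures and any effect of DF.

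The 10 genes most elevated in the DF library included Car3, Aqp7 and Slc25a20. Car3, the adipocyte-rich carbonic anhydrase, was at 7.30 in the control and 9.66 with DF, 5.14-fold higher. Aqp7, the glycerol channel of fat cells, was 4.16-fold higher (7.36 to 9.42), and Slc25a20, the mitochondrial carnitine-acylcarnitine carrier, 4.49-fold higher (6.34 to 8.51). Pex2, a peroxisome biogenesis factor, was 5.80-fold higher, and Gstk1, a mitochondrial and peroxisomal glutathione transferase, 4.55-fold. Also among the 10 highest were Acp5 (tartrate-resistant acid phosphatase), Cacna1c (an L-type calcium channel subunit), the C-type lectin gene Clec2i and the TWEAK receptor gene Tnfrsf12a. Acp5 had the largest difference, 6.48 log2 units, from 1.81 in the control, close to the bottom of the scale. Car3 lies at chromosome 3, 14863512 to 14872523 on the plus strand, and Aqp7 at chromosome 4, 41033074 to 41048139 on the minus strand (GRCm38). Each of those named exceeded all of the 200 genes nearest in level, except Aqp7, which exceeded 199. This follows largely from their choice as the largest differences. All of them lay below the level floor of 8.18 in the control library and were examined only through their DF values. Cacna1c and Clec2i overlap a coding gene on the other strand, and Clec2i has close relatives, so their reads are less certain.

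The 10 genes lowest in the DF library relative to the control included Dnmt3b, Sgcd and Crtc2. Dnmt3b, a de novo DNA methyltransferase, was at 8.71 in the control and 4.27 with DF, 21.8-fold lower. Sgcd, a sarcoglycan of the dystrophin complex, was 23.7-fold lower (8.49 to 3.92). Crtc2, a coactivator of CREB, was 8.19-fold lower, and Aff1, a component of the super elongation complex, 6.21-fold. Arhgap32 and Arhgef10l were 6.72-fold and 6.18-fold lower. Synj2, a phosphoinositide phosphatase, the zinc finger gene Zscan21 and Ly6c1, a surface antigen with a near-identical neighbour, were 6.71-fold, 6.35-fold and 6.52-fold lower. Styxl1, at 8.60 in the control, was listed at 0 with DF, for which no fold is given. Only Arhgef10l (10.45), Aff1 (9.81) and Synj2 (9.24) of these 10 were above 9 in the control library. Synj2 overlaps Serac1 on the genome, so its reads are less certain, as are those of Ly6c1.

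**Figure D1:**
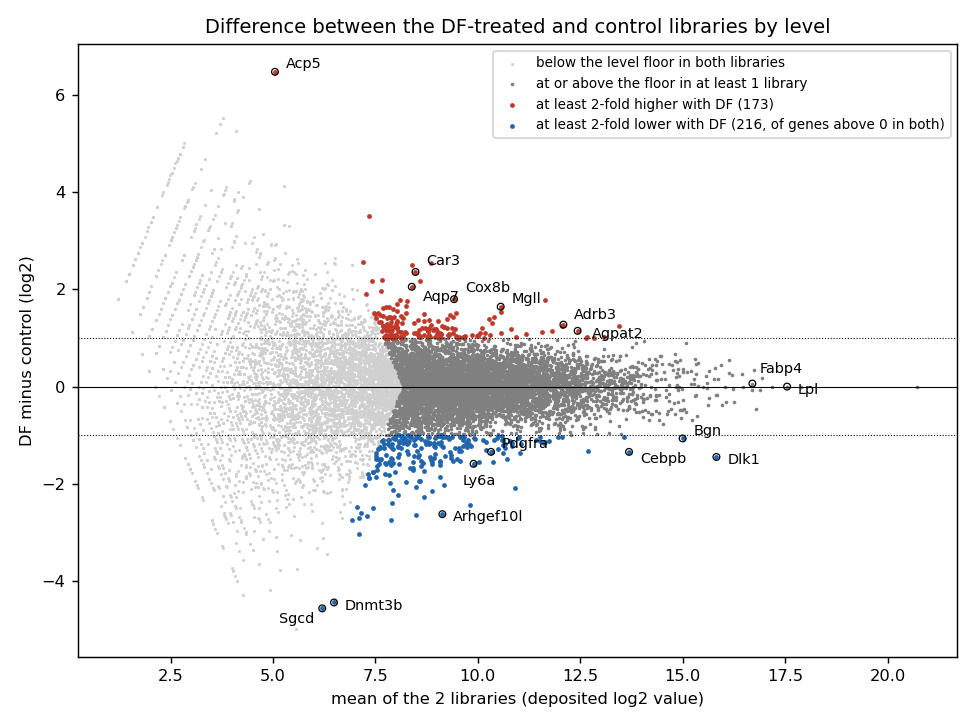
Each point is a gene above 0 in both libraries, with the mean of the 2 deposited log2 values on the x axis and DF minus control (log2) on the y axis; dotted lines mark 2-fold. The scatter narrows with level, and Dlk1, Cebpb and Bgn lie below the 2-fold line among abundant genes, whereas Lpl and Fabp4 lie near 0; Styxl1, listed at 0 with DF, is not drawn.

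The master regulators of fat-cell formation were at nearly equal levels in the libraries, while Cebpb and Cebpd were lower with DF. Pparg, the nuclear receptor that drives adipogenesis, was at 11.94 in the control and 11.84 with DF, and Cebpa at 15.56 and 15.64. Srebf1, the regulator of lipogenic genes, was at 9.55 and 9.42. Cebpb, which acts early in differentiation, was 2.54-fold lower with DF (14.36 to 13.02), below each of the 200 genes nearest in level. Cebpd, its early partner, was 1.60-fold lower, and Ebf2, a factor of brown and beige fat precursors, 1.63-fold higher. Of 17 examined factors, 2 were higher by at least 1.5-fold and 2 were lower, and the median of 20 members was -0.10 log2 units (bootstrap interval -0.32 to 0.16), at percentile 15.5 of matched random lists. Cebpb lies at chromosome 2, 167688915 to 167690418 on the plus strand, where it overlaps Tmem189 on the other strand. Cebpd and Srebf1 also overlap a coding gene on the other strand (Spidr and Rai1), as do Acaa1a, Cox6c and others named below. Whether counting separated the strands is not given in the sources used here.

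Markers of mature adipocytes were mostly near equal or higher with DF. Of 23 examined, 9 were higher by 1.5-fold and 0 lower, and the median of 24 members was 0.41 log2 units (interval 0.21 to 0.81), above all 10000 random lists. Several abundant markers differed little. Lpl, lipoprotein lipase, stood at 17.55 in both libraries, Fabp4, the fatty acid binding protein, at 16.67 and 16.73, and Slc2a4, the insulin-responsive glucose transporter, at 12.46 in both. Lpl and Fabp4 are among the highest genes, whose sorted values are identical in both files, so their values compare ranks rather than amounts. The same limit holds for Adipoq and Cfd. It also holds for genes named below such as Scd1, Pnpla2, Atp5g3, Dlk1, Bgn, Col6a3 and Fn1, whose folds come from ranks too. Adipoq, which encodes adiponectin, was 1.18-fold higher (16.08 to 16.32), Cfd, which encodes adipsin, 1.26-fold, and Plin1, the lipid droplet coat protein, 1.28-fold. Cd36, the fatty acid translocase, was 1.54-fold higher (14.14 to 14.77), above 193 of the 200 nearest genes. Adrb3, the adrenergic receptor of fat cells, was 2.42-fold higher (11.45 to 12.73). Lep, which encodes leptin, was at 3.92 and 6.12, below the level floor in both.

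**Figure D2:**
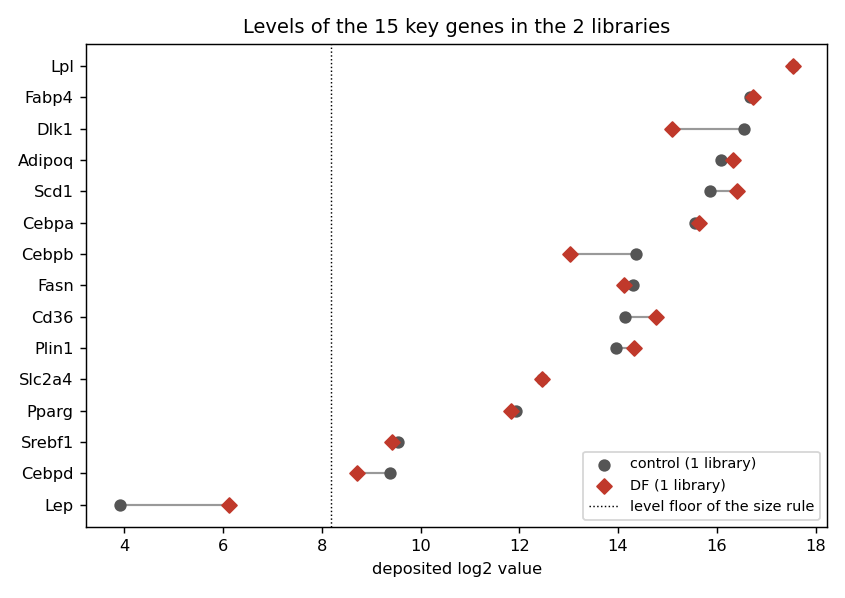
The x axis gives the deposited log2 value of each of the 15 key genes, with circles for the control library, diamonds for the DF library and a dotted line at the level floor of 8.18. Dlk1 and Cebpb have the widest gaps towards lower values with DF, and both symbols overlap for Lpl and Slc2a4.

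The lipolysis median lay above the central 95% of matched random lists. That of fatty acid and triglyceride synthesis lay just below the upper limit of its own random lists. In fatty acid and triglyceride synthesis, 4 of 21 examined members were higher by 1.5-fold and 0 lower. The median was 0.20 (interval 0.08 to 0.49) at percentile 96.7, within the central 95% of random lists (upper limit 0.21). Over members at the level floor the median was 0.23. Agpat2, an acyltransferase of triglyceride synthesis, was 2.22-fold higher, Gpd1, which supplies the glycerol backbone, 1.91-fold and Acacb, an acetyl-CoA carboxylase, 1.78-fold. Agpat2 meets the end of Egfl7 on the other strand, which was 1.83-fold higher. Scd1, the stearoyl-CoA desaturase, was 1.47-fold higher (15.85 to 16.41), Acsl1, which activates fatty acids, 1.11-fold higher, and Fasn, fatty acid synthase, was at 14.30 and 14.12. In lipolysis, 5 of 14 were higher and 0 lower, with a median of 0.36 (interval 0.06 to 0.87) at percentile 99.6. The intervals of the synthesis and lipolysis lists overlapped, so the lists are not shown to differ from each other. Mgll, the monoglyceride lipase, was 3.13-fold higher (9.74 to 11.38), and Pnpla2, the first triglyceride lipase of the pathway, was at 16.32 and 16.58. The lipolysis list shares Fabp4, Plin1, Lipe, Aqp7 and Adrb3 with the mature adipocyte list, so these lists are not independent.

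The beta-oxidation and oxidative phosphorylation lists had higher medians with DF than matched random lists, although most members lay within 1.5-fold. In fatty acid beta-oxidation, 5 of 18 members were higher and 1 lower, with a median of 0.35 (interval 0.17 to 0.54), which 12 of 10000 random lists reached or exceeded. Etfa, an electron transfer flavoprotein subunit, was 1.70-fold higher and Acadvl, the very long chain acyl-CoA dehydrogenase that overlaps Dvl2 on the genome, 1.55-fold, whereas Etfb, the most abundant member, was at 13.81 and 13.85 and the peroxisomal thiolase Acaa1a was 1.60-fold lower. The 46 nuclear genes of oxidative phosphorylation had a median of 0.26 (interval 0.14 to 0.37), above 9998 of 10000 random lists, and 6 were higher by 1.5-fold and 1 lower. Cox6c and Cox5b, subunits of cytochrome c oxidase, were 1.87-fold and 1.80-fold higher, Cox8a was 1.56-fold higher and Atp5g3, of the ATP synthase, 1.12-fold. Sdhd, a subunit of succinate dehydrogenase, was 2.87-fold lower (9.85 to 8.33). Among 8 thermogenic genes above 0 in both libraries, the median of 0.06 lay at percentile 49.8; over the 5 at the level floor, 3 of them higher by 1.5-fold and 0 lower, it was 0.62. Cox8b was 3.48-fold higher (8.52 to 10.32), Cox7a1 1.86-fold and the potassium channel gene Kcnk3 1.54-fold, whereas Ppargc1b was at 9.73 and 9.80; Ucp1, the uncoupling protein of brown fat and named after its values were seen, was listed at 0 in both.

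Cytosolic ribosomal protein genes had a lower median with DF, although most examined members lay within 1.5-fold. Of 78 examined, 28 were lower by 1.5-fold and 1 was higher, and the median of 80 members was -0.46 (interval -0.56 to -0.38), below all 10000 random lists. Rps3a1 was at 13.35 and 12.02 (difference -1.32), Rps4x and Rps27a each 2.06-fold lower, and Rpl22, the most abundant, 1.52-fold lower, whereas Rpl32 was at 14.85 and 14.84. Ribosomal protein genes have many processed pseudogenes, and how reads that fit several copies were treated is not given in the sources used here.

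The matrix list had a lower median with DF, and some preadipocyte and contractile genes were lower. Dlk1 (Pref-1), the preadipocyte factor that restrains differentiation, was at 16.55 in the control and 15.10 with DF, 2.73-fold lower. Its difference lay below that of each of the 200 other genes at the top of the scale. Ly6a, which encodes the progenitor antigen Sca-1, was 3.01-fold lower (10.69 to 9.10) and Pdgfra, a receptor of mesenchymal precursors, 2.54-fold (10.99 to 9.65), whereas Ctnnb1, which encodes beta-catenin, was at 12.78 and 12.65. In that list 3 of 9 examined members were lower and 1 higher, and its median of -0.20 (interval -0.57 to 0.32) was matched or undercut by 702 of 10000 random lists, within the central 95%. In the extracellular matrix list 5 of 26 were lower and 0 higher, and the median of 33 members was -0.35 (interval -0.47 to -0.23), below 9998 of 10000 random lists. Bgn, the proteoglycan biglycan, was 2.10-fold lower (15.53 to 14.46), Thbs1, which encodes thrombospondin, 2.15-fold (8.37 to 7.27) and the collagen gene Col1a2 1.70-fold (14.89 to 14.13). Col6a3 and Fn1, which encodes fibronectin, the most abundant of the list, were 1.38-fold and 1.24-fold lower. In the myofibroblast list 3 of 5 examined members, the tropomyosin genes Tpm1 and Tpm2 and the calponin gene Cnn2, were 1.85-fold, 2.01-fold and 1.88-fold lower, Cald1 was 1.49-fold lower, and the median of 8 members was -0.49 (interval -0.91 to 0.81) at percentile 2.17. Dlk1 lies at chromosome 12, 109452823 to 109463336 on the plus strand, and Bgn at chromosome X, 73483602 to 73495933 on the plus strand.

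The inflammatory and acute-phase list had a lower median with DF, although many of its members lay below the level floor. Of 9 examined members 3 were lower by 1.5-fold and 0 higher, and the median of 19 members was -0.31 (interval -0.90 to -0.07) at percentile 1.84. Csf1, the macrophage colony-stimulating factor gene, was 2.09-fold lower (9.49 to 8.42), the adhesion molecule gene Vcam1 2.07-fold (9.82 to 8.77) and the chemokine gene Cxcl12 1.57-fold (13.05 to 12.39). C3, the complement component and most abundant member, was 1.24-fold lower. Among 19 adipokine genes 0 of 14 examined differed by 1.5-fold, with a median of 0.24 at percentile 92.4. The interferon list of 17 members had a median of 0.04 at percentile 42.7, with Ifi35 2.18-fold lower and Irf9 1.25-fold higher.

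**Figure D3:**
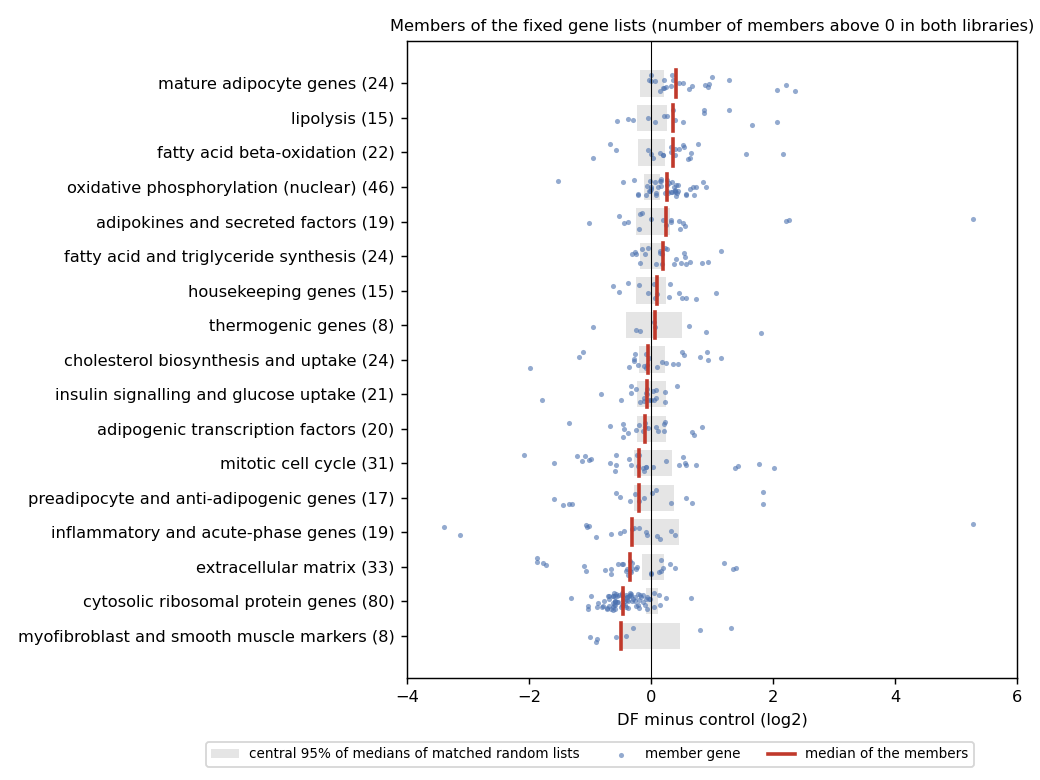
Each line holds 1 of the fixed gene lists; points are member genes by DF minus control (log2, x axis), the red bar is their median and the grey band the central 95% of medians of 10000 random lists matched on level. The medians of the mature adipocyte, lipolysis, beta-oxidation and oxidative phosphorylation lists lie above their bands, and those of the inflammatory, extracellular matrix, ribosomal protein and myofibroblast lists below; the skeletal muscle list, also above its band, is not drawn.

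Lists for sterol synthesis, insulin signalling, the cell cycle and stress also had medians within the central 95% of random lists. Among cholesterol genes the median was -0.05 (2504 of 10000 random lists at or below), and single members went both ways. Srebf2, the sterol-responsive transcription factor, was 2.21-fold higher and Sqle, squalene epoxidase, 1.91-fold higher, whereas Idi1, the isopentenyl diphosphate isomerase, was 2.17-fold lower; Hmgcs1 was 1.16-fold lower. In insulin signalling 0 of 17 examined genes differed by 1.5-fold, with a median of -0.07 (percentile 22.5); Akt2 was 1.17-fold higher. In the cell cycle list the median of 31 members was -0.19 (percentile 7.17). The E-type cyclins went apart, Ccne1 2.58-fold higher and Ccne2 2.11-fold lower; Ccna2 was 1.66-fold higher, Kif20a 1.29-fold lower and E2f1 1.08-fold lower. For glycolysis the median was 0.10 (percentile 81.5), with Pfkp 1.53-fold higher, Pfkm 1.58-fold lower, Aldoa at 16.73 and 16.67, and Ldha at 14.63 and 14.55.

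The stress and signalling lists below, from Nrf2 to the clock genes, had medians within the central 95% of random lists. All of these but the aryl hydrocarbon receptor list held at least 1 examined member beyond 1.5-fold. The Nrf2 list had a median of 0.15 (percentile 88.9), with Gclm 1.76-fold and Hmox1 1.64-fold higher, Gsr 1.75-fold lower, Fth1 1.04-fold lower and Tkt 1.23-fold higher. The aryl hydrocarbon receptor list had a median of 0.08 (percentile 44.6); Tiparp was 1.25-fold higher and Cyp1b1 1.07-fold lower. For unfolded protein and integrated stress genes the median was 0.00 (percentile 48.1), with Hspa5 at 16.47 in both, Atf5 1.48-fold higher and Manf 1.66-fold higher. The heat shock median was -0.03 (percentile 40.4), with Cryab 2.34-fold lower, Chordc1 1.99-fold lower, Hsph1 1.56-fold higher, Hspd1 1.11-fold lower and Hsp90aa1 1.01-fold higher. The p53 target median was 0.00 (percentile 40.8); Sesn1, Bax and Gdf15 were 1.80-fold, 1.67-fold and 1.65-fold higher, Cdkn1a was 1.34-fold higher, and Mdm2, the fourth most abundant gene in both libraries, was at 17.19 in each. The glucocorticoid list had a median of 0.01 (percentile 48.2), with Dusp1 2.09-fold higher, Fkbp5 1.87-fold lower, and the metallothionein genes Mt1 and Mt2 1.17-fold and 1.01-fold higher. Immediate early genes had a median of 0.12 (percentile 71.6), with Ier2 1.52-fold lower, Junb 1.39-fold higher and Egr1 1.11-fold lower. Clock genes had a median of 0.00 (percentile 45.2), with Nr1d2 1.65-fold lower, Tef 1.08-fold lower and Per1 1.22-fold higher.

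Markers of other cell types were mostly near the bottom of the scale in both libraries. Of 13 macrophage markers 3 were above 0 in both, among them Ptprc (4.33 and 2.64) and Cd68 (2.83 and 4.88), and their median of 0.58 lay at percentile 43.1. Of 12 endothelial markers 4 were above 0 in both, led by Eng, 1.14-fold higher, and Egfl7; their median was -0.34 (percentile 18.4). Of 10 epithelial markers, Krt18 alone was above 0 in both, at 7.31 and 5.15. Of 13 skeletal muscle markers 3 were above 0 in both, with Des 1.55-fold higher (9.79 to 10.43) and Acta1 at 1.00 and 6.54, and their median of 2.96 lay at percentile 99.5. Of 12 osteoblast and chondrocyte markers 3 were above 0 in both, with a median of 0.63 (percentile 87.0), Spp1 2.38-fold higher and Runx2 1.19-fold lower. The 15 housekeeping genes had a median of 0.10 (interval -0.06 to 0.46) at percentile 80.1. Among them Tfrc, the transferrin receptor gene, was 2.09-fold higher, whereas Eef1a1 was 1.43-fold and Rplp0 1.53-fold lower. Mitochondrially encoded genes were not analysed here. Across 31 lists with at least 3 members, 9 medians lay outside the central 95% of random lists. Random lists of independent genes would give 1.55. Members of a list can vary together and some lists share members, so 1.55 is no chance rate for these lists.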

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

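The counts of genes depended on where the limits were set and some medians of short lists on which members entered. At least 2-fold differences were seen in 173 higher and 217 lower genes; these became 1688 and 1974 with no level floor, 541 and 573 with a floor of 6, and 39 and 68 with a floor of 10 (log2). A 1.5-fold limit gave 693 and 735 genes, and a 3-fold limit 23 and 52. Pseudocounts of 0.1, 1 and 5 on the linear value, centring, and removal of the trend in 3' GC content and length gave 158 to 173 higher and 211 to 228 lower genes. Of 238 alternative list medians, 237 stayed within the bootstrap interval of the reported median and 0 of those whose reported median lay outside the central 95% of random lists changed sign; the exception was the adipokine list, whose mean was 0.52 against a median of 0.24. The bootstrap intervals are wide for short lists. Centring shifted every value by 0.01 log2 units, and pseudocounts move values far above 0 little. Many of the alternative values, those of the named genes below included, could therefore hardly move. The thermogenic median of 0.06 became 0.62 over members at the floor, and the adipokine median 0.10. For lists, the trend was removed over members at the floor only, which changes 2 choices together; it gave 0.53 and 0.11 there, so most of the move came from the restriction of members. With no minimum the interferon median of 0.04 became -0.58 and the endothelial median of -0.34 became 0.19, and the osteoblast and chondrocyte median of 0.63 also 0.19. The myofibroblast median of -0.49 became -0.88 with no minimum or over members at the floor, and its mean was -0.25. The skeletal muscle median of 2.96 became 1.24 with a pseudocount of 5. Of 690 alternative values of named genes, 689 moved by less than the SD of the nearest 200 genes and 0 of those counted at 1.5-fold changed sign; the exception was Acta1, whose difference was 3.81 in place of 5.54 with a pseudocount of 5. The linear value to which pseudocounts were added was redefined, from 2 to the power of the deposited value minus 1 to that power itself, after the steps of the low values had been seen. The floors of 6 and 10, the pseudocount of 1, centring, the GC and length trend and the restriction of lists to members above the floor were chosen after seeing the data. Total-count, median-of-ratios, upper-quartile and top-gene scaling, count minimums and counting intervals were not run, since they need read counts. No paired analysis was possible because each group holds 1 library, and no library could be left out. Precision is limited by this and by the unknown depth.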

Other observations

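Medians of some gene families grouped by symbol also lay apart from matched random lists. The 25 families were chosen after the gene table had been seen, and some symbol patterns were narrowed after a first look at their values to leave out genes that are not members. Medians of 6 families lay outside the central 95% of matched random lists. Random lists of independent genes would give 1.25, which is no chance rate for families chosen in this way. Some families share members with the fixed lists, so these family medians partly repeat them. Vacuolar ATPase genes, which encode the proton pump of lysosomes, had a median of 0.36 over 18 members, with 2 of 16 examined higher by 1.5-fold and 0 lower. Atp6v0b was at 11.02 in the control and 11.92 with DF, Atp6v0d1 at 10.65 and 11.28, and Atp6ap1 at 14.02 and 14.48. Mitochondrial ribosomal protein genes had a median of 0.18 over 77 members (percentile 99.4), with 16 of 64 higher and 3 lower. Mrpl3 was at 10.02 and 11.12 and Mrps23 at 12.57 and 12.95, whereas Mrps6 was at 13.03 and 12.94.

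The translation elongation factor family had a lower median with DF, as did the cytosolic ribosomal protein list. The elongation factor median was -0.59 over 6 members (percentile 0.160), with 3 of 5 examined lower by 1.5-fold and 0 higher. Eef1b2 was at 13.85 and 13.05, Eef2 at 15.29 and 14.63, and Eef1g at 11.35 and 10.70. Collagen genes, which overlap the extracellular matrix list, had a median of -0.32 over 24 members (percentile 0.150); Col1a1 was at 13.95 and 13.29, but Col6a1 at 12.43 and 12.82. ADAM and ADAMTS protease genes had a median of -0.38 (percentile 0.570), with Adam9 at 9.12 and 6.72. Proteasome genes (0.03, percentile 53.9) and translation initiation factor genes (-0.00, percentile 40.3) lay in the middle of the random lists.

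The tests for a trend with level, for a difference between cultures and for genes with 3 transcripts were chosen only after the result was seen. The mature adipocyte and extracellular matrix medians lay 0.70 log2 units apart, over 23 and 26 genes at the level floor. After removal of the trend in 3' GC content and transcript length the gap was 0.63 (bootstrap interval 0.40 to 1.01, treating genes as independent), which argues against that trend as the whole cause. Pairs of random lists matched on level had a median gap of 0.00365 (central 95% -0.27 to 0.28). Both medians had already been found outside the central 95% of random lists matched on level. The gap of such random lists repeats that step, so it is no independent check of a trend with level. Across 6545 genes at or above the level floor, the Spearman rho of the difference with mean level was -0.00666. A difference between the cultures or library preparations apart from DF cannot be told apart from the treatment, because there was 1 library per group. An effect of DF stays open as untested.

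The median of 78 ribosomal protein genes at the level floor was -0.46. It was -0.56 (interval -0.62 to -0.48) after removal of the GC and length trend. Short transcripts as a class had no such shift, since 234 genes matched on length and level had a median of 0.10 (interval 0.04 to 0.15). Both values argue against these technical explanations. A difference between cultures or library preparations stays open with 1 library per group, as does an effect of DF, which was not tested.

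Low values lie on discrete steps, and their pattern may come from reads counted once per annotated transcript; no biological explanation was tested. Among the lowest 60 steps, genes with 2 RefSeq transcripts fell on even steps for 67.8% of 618 values in the control library and genes with 1 transcript for 49.3% of 2034 (exact intervals 64.0 to 71.5 and 47.1 to 51.5), and the difference in the DF library was 18.3 percentage points. Where both transcripts ended within 50 nt the share was 13.8 points higher than where they ended over 500 nt apart (82.2% of 304 and 68.5% of 257 values). These values pool both libraries, so a gene can enter more than once, although the exact interval treats values as independent. Genes with other or unknown distances between the ends were left out here. The share at ends far apart (exact interval 62.4 to 74.1) still lay above that of genes with 1 transcript, so a shared end does not account for all of the pattern, and the explanation stays open. Genes with 3 transcripts leave it open too. In the DF library steps divisible by 3 held 46.4% of 196 values (31.8% for genes with 1 transcript). In the control library they held 25.2% of 246, and the series starting at step 1 held 54.5% (36.6% for genes with 1 transcript). Steps were numbered by order among each library's own values, with step 1 at 1.25 in the control and 4.375 in the DF library (linear). The fullest series can thus differ through the numbering alone, so this comparison cannot decide.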
